A study of Homo sapiens with 6 samples.

How the data were processed

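Messenger RNA was sequenced from 6 samples of THP-1, a human acute monocytic leukaemia cell line. By the labels, 3 samples carried an empty vector (vector) and 3 carried a construct that overexpresses the inhibitory receptor CD300A (oeCD300A). Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with an Illumina stranded mRNA kit. Per the submitters' processing notes, the tools fastp and HISAT2 and the genome build GRCh38 (hg38) were used. Their versions, the read counter, the annotation release and the tool that made the expression values are not given in the sources used here.

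The authors deposited a single table of TPM values, a length-normalized share of transcripts that sums to the same total in every library, rounded to 2 decimals, with 78893 genes, a column per sample and gene annotation that includes KEGG pathways. The authors' mean TPM per group stood beside them, and these differed from the means of the sample columns by less than 1e-04 TPM. They were not used further. TPM scales every library to the same sum, so the sequencing depth of each library is unknown, and no counting interval or detection limit can be given. A gene at exactly 0 is therefore described as listed at 0. TPM is also a share: a change in a few very abundant genes moves all others slightly.

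The tested genes were the 15318 with a TPM of at least 1 in at least 3 of the 6 libraries. Values were analysed as log2(TPM + 1), so every log2 change is on that scale and understates the change of low genes. The oeCD300A and vector groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided, Benjamini-Hochberg adjustment over all tested genes, threshold 0.05, data.table, version 1.17.8, for reading). All 6 libraries entered 1 fit with no covariate. CD300A was also tested by an exact two-sided permutation test over the 20 assignments of the 6 libraries, whose smallest possible p is 0.1. No count test was run, since TPM values are not counts.

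Before the data were examined, 37 gene lists were fixed, with 1006 distinct symbols, of which 752 genes were tested. Each list was tested with camera (inter-gene correlation preset at 0.01, lists with at least 5 tested members, CD300A left out, Benjamini-Hochberg adjustment over the lists), with camera at an estimated correlation, and with fry. Counts given as adjusted over the list alone (higher, then lower) adjust the limma p within that list only, with no adjustment over the lists. That threshold is usually looser than the one over all tested genes. Camera compares the members with the other tested genes. Since the median log2 change of all tested genes was 0.0585, a list that camera calls lower or downward need not have fallen. KEGG pathways with 15 to 300 tested members were tested with camera in the same way, 300 in all.

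The genes named were also chosen by a rule fixed beforehand. They were CD300A, JAK2, STAT3, SOCS3, IL10, CD163, MRC1, ARG1, MSR1, TGFB1, CD80, CD86, TNF, IL1B, IL6, NOS2, CCL2, VEGFA and MMP9, whatever their values. Added to these were the 10 largest positive and 10 largest negative log2 changes among genes past the threshold whose groups did not overlap and whose mean TPM was at least 5 in the higher group. From each list came the 3 tested members with the smallest adjusted p, or 4 where the list passed camera. Genes named outside this rule are said to be so. Not every gene that the rule takes is reported here.

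The fit was tested on simulated data with the real genes' means and spread over 15318 genes. For oeCD300A against vector it recovered 28.4% of genes changed by 0.5 on the log2 scale, 76.1% of those changed by 1 and 98.5% of those changed by 2. Of the simulated calls, 2.17% were false, and 1 gene was called when no gene had been changed. Genes were drawn independently of each other, without variation shared within a library, so these rates need not hold for the real libraries.

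The alternatives were other pseudocounts (0.1 and 0.5), no filter, a mean TPM of at least 5, median-ratio scaling, quantile normalization, rescaling without mitochondrially encoded genes and CD300A, the replicate number as a block, library quality weights, robust eBayes, eBayes without trend, leaving out each library, and camera with an estimated correlation. Alternatives chosen after seeing the data were protein-coding genes only, a loess correction for GC content and transcript length (span 0.3), and leaving out a raised run of genes on chromosome 1. Gene positions, GC content and transcript lengths came from GENCODE release 29 (GRCh38, the build of the submitters' notes) through Ensembl gene IDs. GC and length values were found for 14103 of the tested genes (92.1%). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Genes with near-identical copies, such as FCGR2B and FCGR2C, HLA class II genes, GSTM genes and histone genes, are uncertain, because it is not known how reads shared between copies were counted.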

Results

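RNA-seq was used to ask how overexpression of CD300A, an inhibitory receptor of myeloid cells, alters the transcriptome of THP-1 cells. THP-1 is a monocytic leukaemia line widely used as a model of human monocytes and macrophages. The series places the question in glioblastoma, M2 macrophage polarization and JAK2/STAT3 signalling. There were 3 libraries with empty vector and 3 with the CD300A construct. Between 26536 and 27136 genes had a TPM above 0 per library, and between 15089 and 15526 reached a TPM of 1. Pairwise correlations of log2(TPM + 1) lay between 0.975 and 0.989. The first principal component held 36.5% of the variance and separated the groups, with vector libraries between -17.6 and -16.6 and oeCD300A libraries at 31.1, 10.8 and 9.49. oeCD300A replicate 1, at 31.1, stood apart from the other oeCD300A libraries. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

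CD300A itself was higher in every oeCD300A library than in any vector library. This gene (ENSG00000167851) lies on the forward strand of chromosome 17, from 74466399 to 74484796 (GRCh38). Its TPM was 21.17, 20.72 and 24.03 with the vector and 45.3, 35.98 and 35.66 with the construct. The means were 21.97 ± 1.80 and 39.0 ± 5.48 (SD, n = 3 each), a 1.77-fold difference. The log2 change was 0.79 with a standard error of 0.11 (limma adjusted p = 0.0125). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give. The limma adjusted p was 0.0721 without vector replicate 1, 0.0643 without vector replicate 2 and 0.0512 when genes of any level were tested.

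**Figure D1:**
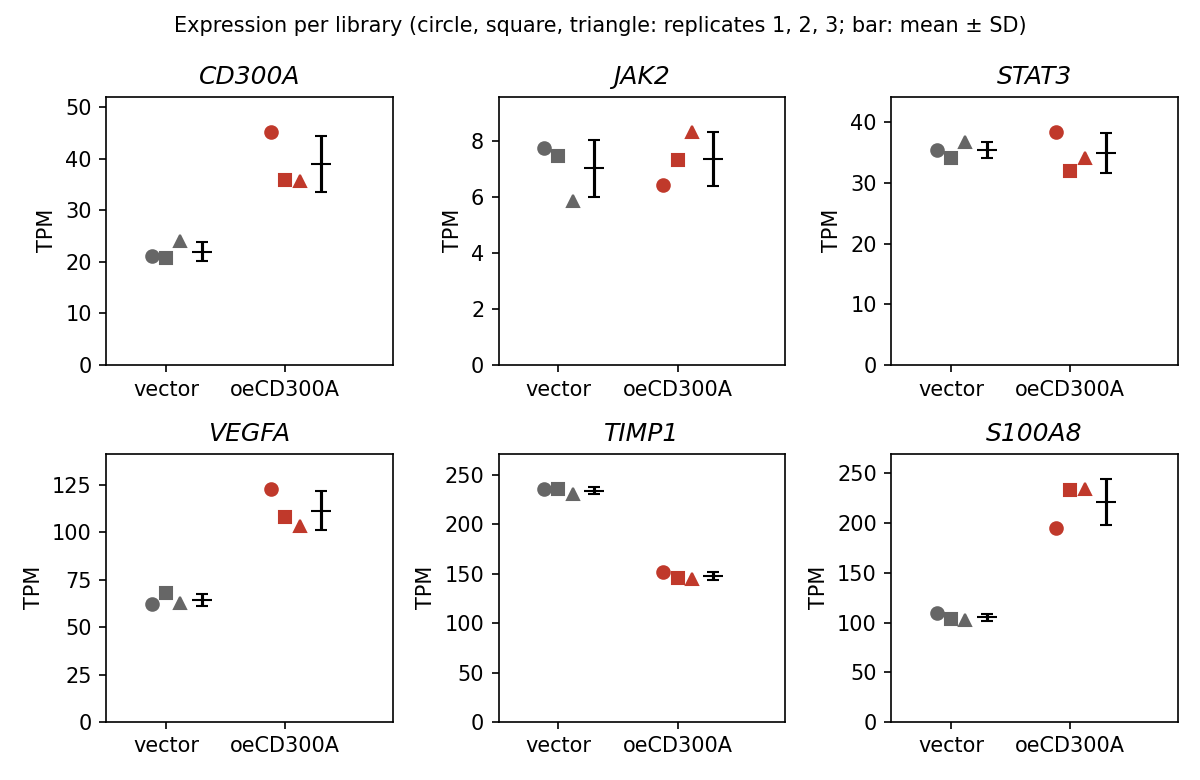
TPM of 6 genes in each library, grey for vector and red for oeCD300A, with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean ± SD (n = 3). CD300A, VEGFA and S100A8 were higher and TIMP1 lower in all 3 oeCD300A libraries than in any vector library, while JAK2 and STAT3 overlapped between the groups.

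Across the transcriptome, 459 genes were higher and 274 lower with CD300A overexpression, and 57 of them changed at least 2-fold on the log2(TPM + 1) scale (33 higher, 24 lower). The largest rises were in HLA-DPB1, HLA-DPA1 and HLA-DRA, chains of MHC class II molecules, in the low-affinity IgG receptors FCGR2B and FCGR2C, and in S100A12, a calcium-binding protein of monocytes and neutrophils. HLA-DPB1 rose from 5.28 to 19.5 TPM, a log2 change of 1.70 (SE 0.09, limma adjusted p = 0.00049). HSPA7 (log2 change 1.60), USH1C (1.29), STC2 (1.22) and TBC1D30 (1.16) completed the 10 largest rises. FCGR2B, FCGR2C and HSPA7 lie beside each other on chromosome 1 and have near-identical copies, so their values are uncertain. The largest fall was in BEX1, from 32.9 to 8.22 TPM (log2 change -1.89, SE 0.13, limma adjusted p = 0.00145). It was followed by CFP, which encodes the complement factor properdin (-1.77), the histone gene H2AC18 (-1.76), SUSD3 (-1.43), the histone gene H2BC9 (-1.23) and the leukocyte surface antigen CD52 (-1.21). PINLYP (-1.20), GLIPR1 (-1.19), EPAS1, which encodes the hypoxia-inducible factor HIF-2α (-1.13), and MS4A6A (-1.11) completed the 10 largest falls. Of the tested genes, 3524 had an unadjusted limma p under 0.05, and in 4660 (30.4%, where chance gives 10%) the groups did not overlap.

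These counts moved with single libraries and with the scaling. The numbers of higher and lower genes were 67 and 32 without vector replicate 1, 98 and 47 without vector replicate 2, 114 and 55 without vector replicate 3, 830 and 779 without oeCD300A replicate 1, 141 and 86 without oeCD300A replicate 2, and 161 and 82 without oeCD300A replicate 3. Higher genes made up 62.6% of the calls, against 47.6% after median-ratio scaling (401 higher, 442 lower), 47.3% after quantile normalization (387 higher, 431 lower) and 51.6% without oeCD300A replicate 1.

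Genes of the hypoxia response rose together. Of 21 tested members, 17 rose and none fell (17 and 0 adjusted over the list alone), and the mean log2 change was 0.67 (camera adjusted p = 4.82e-17, and adjusted p = 0.0238 with an estimated correlation). VEGFA, the angiogenic growth factor, went from 64.3 ± 3.04 to 111 ± 10.4 TPM (SD, n = 3 each), a log2 change of 0.78 (SE 0.08, limma adjusted p = 0.00503). The mitophagy receptor BNIP3 went from 98.2 to 162 TPM (log2 change 0.71), the lipid droplet protein HILPDA from 39.0 to 71.0 (0.84) and the collagen prolyl hydroxylase P4HA1 from 48.4 to 84.2 (0.78). SLC2A3, a glucose transporter counted both here and among the glycolysis genes, went from 5.63 to 13.1 TPM (1.09). The list mean was higher in each oeCD300A library (5.28 to 5.35) than in each vector library (4.62 to 4.66).

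Most glycolysis genes rose as well. Of 23 members, 13 rose and none fell (20 and 0 adjusted over the list alone), with a mean log2 change of 0.49 (camera adjusted p = 1.16e-12, but adjusted p = 0.35 with an estimated correlation). The aldolase ALDOC went from 91.5 to 202 TPM (log2 change 1.13), the hexokinase HK2 from 18.2 to 33.4 (0.84) and the enolase ENO2 from 11.9 to 25.6 (1.04). The glycolysis list mean was largest in oeCD300A replicate 1, at 7.62, against 7.43 and 7.46 in the other oeCD300A libraries and 6.999 to 7.05 with the vector. SLC16A1, a lactate transporter among the risers named after its values were seen, lies in a stretch of chromosome 1 where 45 of 112 tested genes rose.

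The cholesterol synthesis list and the ATF4 and unfolded protein response list were also higher on average. In the cholesterol list 12 of 24 members rose and none fell (16 and 1 adjusted over the list alone), with a mean log2 change of 0.36 (camera adjusted p = 9.24e-09, and adjusted p = 0.0651 with an estimated correlation). INSIG1, a regulator of sterol sensing, went from 152 to 215 TPM (0.50), the lipid transfer protein STARD4 from 30.1 to 50.5 (0.73), ACAT2 from 82.9 to 119 (0.52) and the synthase HMGCS1 from 91.4 to 143 (0.64). Of 32 members of the ATF4 and unfolded protein response list, 6 rose and 1 fell (15 and 1 adjusted over the list alone), with a mean log2 change of 0.21 (camera adjusted p = 0.0056, but adjusted p = 0.364 with an estimated correlation). The risers included the asparagine synthetase ASNS, from 25.7 to 44.7 TPM (0.78), the pseudokinase TRIB3 (0.70), and PSAT1 (0.45) and PHGDH (0.75) of serine synthesis. PHGDH, at 119648411 to 119744226 of chromosome 1, lies late in the stretch of raised genes described at the end, beside ZNF697 (0.16) and NOTCH2 (0.04), which did not pass. Both of these neighbours are named outside the rule.

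**Figure D2:**
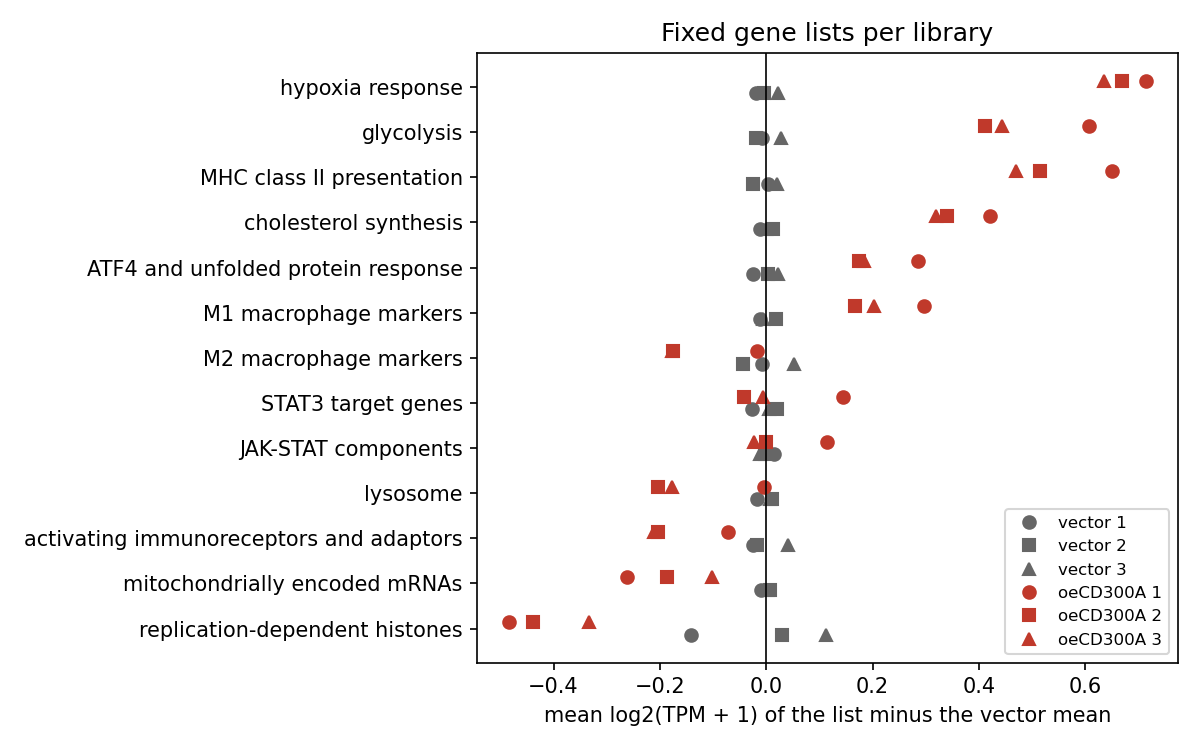
Mean log2(TPM + 1) over the tested members of 13 fixed gene lists in each library, minus the mean of the 3 vector libraries, grey for vector and red for oeCD300A, with circles, squares and triangles for replicates 1, 2 and 3. The hypoxia, glycolysis, MHC class II and cholesterol lists were higher in all 3 oeCD300A libraries, while for lysosome genes oeCD300A replicate 1 lay among the vector libraries.

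MHC class II genes, and a few MHC class I genes, were higher with CD300A overexpression. Of 16 MHC class II genes, 10 rose and none fell (10 and 3 adjusted over the list alone), with a mean log2 change of 0.55 (camera adjusted p = 2.81e-05, but adjusted p = 0.364 with an estimated correlation). HLA-DRA went from 82.8 ± 0.28 to 194 ± 5.93 TPM (SD, n = 3 each; log2 change 1.22), HLA-DPA1 from 8.95 to 27.3 (1.50) and HLA-DRB5 from 69.4 to 118 (0.76). Of 17 MHC class I genes, 3 rose and none fell (8 and 0 adjusted over the list alone), among them HLA-E (0.45) and the immunoproteasome subunit PSMB9 (0.34), with a mean of 0.18 (camera adjusted p = 0.00871, but adjusted p = 0.364 with an estimated correlation). HLA-E lies in a run of 100 neighbouring tested genes on chromosome 6 whose median log2 change was 0.19. The following run, with PSMB9, HLA-DRA, HLA-DPA1 and HLA-DPB1, had a median of 0.18. The class I mean was near these medians, so a shift of the region and a shift of the list were not told apart. The class II mean of 0.55 lay above them.

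The macrophage polarization lists did not pass camera. Of 30 M2 markers 14 could be tested. Of these none rose and 2 fell (0 and 3 adjusted over the list alone), FOLR2 from 2.40 to 0.90 TPM (log2 change -0.84) and VSIG4 from 1.28 to 0.32 (-0.79). The M2 mean log2 change was -0.12 (camera adjusted p = 0.0884, fry adjusted p = 0.225). The median was -0.009, with 7 members positive and 7 negative, so most members did not share the lower mean. The list passed camera as lower without oeCD300A replicate 1 (adjusted p = 0.0299) and without vector replicate 2 (0.0486). Its mean in oeCD300A replicate 1 (3.353) lay within the vector range of 3.326 to 3.42. CD163 (mean TPM 1.02 and 0.38 for vector and oeCD300A), MSR1 (0.38 and 0.22), ARG1 (0.037 and 0.05) and MRC1 (0.0067 and 0.0033) were too low to be tested, and IL10 was listed at 0 in all 6 libraries. Of 30 M1 markers 13 could be tested, 10 of them positive and 3 negative. Of these, 0 passed limma over all genes, 6 had an unadjusted p under 0.05, all higher, and 4 rose adjusted over the list alone. The M1 mean was 0.22 (camera adjusted p = 0.0663), and the list passed fry as higher (adjusted p = 0.024). It passed camera as higher without oeCD300A replicate 2 (0.0400), without the eBayes trend (0.0494) and after GC and length correction (0.0332). TNF was at 7.91 and 10.95 TPM in the vector and oeCD300A groups (log2 change 0.42, limma adjusted p = 0.0976), IL1B at 1.36 and 1.91 (0.30, 0.201) and CD86 at 1.09 and 1.75 (0.39, 0.193). CD80 (0.19 and 0.083 TPM) and NOS2 (0.063 and 0.14 TPM) were too low to be tested, and IL6 was listed at 0 throughout.

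JAK2 and STAT3 transcripts did not pass the test. JAK2 was at 7.03 ± 1.01 and 7.36 ± 0.96 TPM in the vector and oeCD300A groups (SD, n = 3 each; log2 change 0.06, SE 0.13, limma adjusted p = 0.828). STAT3 was at 35.5 ± 1.38 and 34.9 ± 3.30 TPM (log2 change -0.03, SE 0.09, limma adjusted p = 0.889), and its feedback inhibitor SOCS3 at 1.57 and 1.86 (0.15, 0.524). Of 36 JAK-STAT components none rose and the receptor chains IL13RA1 (-0.49) and IL6R (-0.39) fell (0 and 2 adjusted over the list alone; mean 0.03, camera adjusted p = 0.937). Of 24 STAT3 target genes VEGFA rose and TIMP1, an inhibitor of matrix metalloproteinases, fell from 234 to 147 TPM (-0.66), with 1 and 1 adjusted over the list alone. The mean of that list was 0.03 and the camera test, which was downward, did not pass (adjusted p = 0.775). MMP9 was at 2.18 and 1.24 TPM (log2 change -0.51, limma adjusted p = 0.0926), CCL2 at 1.68 and 1.29 (-0.29, 0.585) and TGFB1 at 43.6 and 47.3 (0.09, 0.80). These are RNA levels, and protein phosphorylation was not analysed here.

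Myeloid genes moved in both directions. In the monocyte identity list of 26, 4 rose and 2 fell (6 and 3 adjusted over the list alone), with a mean of 0.10, a median of -0.05 and a downward camera test that did not pass (adjusted p = 0.707). The calprotectin genes S100A8, from 105 to 221 TPM (log2 change 1.06), and S100A9, from 169 to 314 (0.89), rose with S100A12 (1.25). Of 15 activating receptors and adaptors none rose and 3 fell (1 and 4 adjusted over the list alone), the adaptors TYROBP, from 424 to 298 TPM (-0.51), and FCER1G (-0.55), and the lipid receptor TREM2 (-0.39). The mean of that list was -0.16 (camera adjusted p = 0.00318, but adjusted p = 0.364 with an estimated correlation). Of 18 inhibitory receptors and phosphatases, CD300A left out, FCGR2B alone rose (1 adjusted over the list alone), and the list did not pass (mean 0.08 with a downward camera test, adjusted p = 0.937). Of 20 macrophage differentiation genes 2 rose and 3 fell (3 and 7 adjusted over the list alone), with APOE (-0.55) and ABCA1 (-0.51) of lipid export lower and PLIN2 (0.53) and GPNMB (0.42) higher. Its mean of -0.09 had a camera adjusted p of 0.047 (adjusted p = 0.394 with an estimated correlation), and the call ended in several settings, among them without vector replicate 1 (0.0684) and at a mean TPM of at least 5 (mean -0.0084, adjusted p = 0.497). The list mean was 4.749 in oeCD300A replicate 1, within the vector range of 4.747 to 4.779, and 4.64 in each of the other oeCD300A libraries.

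The mean of lysosome genes was lower in 2 of the 3 oeCD300A libraries. Of 37 members none rose and 5 fell (1 and 9 adjusted over the list alone), among them the membrane protein CD63, from 338 to 226 TPM (log2 change -0.57), and the cathepsins CTSZ (-0.75), CTSC (-0.50) and CTSH (-0.52). The list mean was 6.13 in oeCD300A replicate 1, within the vector range of 6.11 to 6.14, and 5.93 and 5.95 in oeCD300A replicates 2 and 3. The mean log2 change was -0.13 (camera adjusted p = 1.77e-05, but adjusted p = 0.366 with an estimated correlation).

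Lists of mitochondrial, histone and ribosome biogenesis transcripts were lower on average, though few members fell. Mitochondrially encoded genes made up 8.48% to 8.63% of TPM in vector libraries and 7.41%, 7.83% and 8.26% in oeCD300A libraries. Of 13 mitochondrially encoded mRNAs none rose and 2 fell (0 and 8 adjusted over the list alone), MT-ND1 (-0.43) and MT-ND6 (-0.28), with a mean of -0.18 (camera adjusted p = 8.79e-08, but adjusted p = 0.394 with an estimated correlation). Of 40 nuclear oxidative phosphorylation genes, ATP5PB rose and NDUFA8 fell (1 and 3 adjusted over the list alone; mean -0.05, camera adjusted p = 0.00406, but adjusted p = 0.394 with an estimated correlation). The mean of oeCD300A replicate 3 (7.749) lay within the vector range of 7.745 to 7.766. That call ended without oeCD300A replicate 1 (mean -0.0083, adjusted p = 0.163), with library quality weights (-0.02, 0.0852) and after quantile normalization (-0.05, 0.17), and ATP5PB lies in the raised stretch of chromosome 1. Of 17 replication-dependent histone genes, whose mRNAs mostly lack the poly(A) tail that mRNA kits select, none rose and 5 fell (1 and 7 adjusted over the list alone). Their mean was -0.42 (camera adjusted p = 4.3e-05, but adjusted p = 0.106 with an estimated correlation), and H2BC12 (-0.89) and H2BC21 (-0.77) fell beside H2AC18 and H2BC9. Of 30 ribosome biogenesis and MYC target genes none rose and ODC1 (-0.45), NOP16 (-0.42) and NOP56 (-0.26) fell (1 and 7 adjusted over the list alone; mean -0.11, camera adjusted p = 0.000148, but adjusted p = 0.364 with an estimated correlation). Of 40 G2/M genes TOP2A rose (0.45) and CDC20 fell (-0.59), with 9 and 1 adjusted over the list alone, and the list was higher on average (0.15, camera adjusted p = 0.00875, but adjusted p = 0.394 with an estimated correlation).

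In all, 14 of the 37 lists passed camera at the preset correlation, 7 higher and 7 lower, and the hypoxia list alone passed with an estimated correlation. The size of the estimate was not always the reason. In the cholesterol list it was 0.0099, near the preset 0.01, yet the unadjusted camera p went from 7.49e-10 to 0.00352. For the hypoxia list it was -0.02, and the unadjusted camera p went from 1.3e-18 to 0.00064. With an estimated correlation, camera also takes its degrees of freedom from the few libraries and not from the many genes. The larger p-values with an estimate therefore need not reflect correlated members, and these effects were not separated for each list. By fry, 14 lists, not all of them the same, moved on balance one way and 35 had members that changed in either direction. Lists that passed camera but not fry were lysosome (fry adjusted p = 0.12), nuclear oxidative phosphorylation (0.376) and activating receptors and adaptors (0.0988). Ribosome biogenesis and MYC targets (0.0511) and macrophage differentiation (0.138) did not pass fry either. Marker lists of other cell types did not pass camera, but 2 of the 5 passed fry. Of 6 tested epithelial and HEK293 markers GAL (-0.69) and KRT17 (-0.82) fell, and CLDN7 (0.55) rose when adjusted over the list alone (1 and 2). With 3 members positive and 3 negative, the list passed fry as lower (camera adjusted p = 0.234, fry adjusted p = 0.0027). Of 5 lymphocyte markers TRAC fell (-0.85, 0 and 1 adjusted over the list alone, camera adjusted p = 0.845), and of 7 fibroblast markers MYL9 fell (-0.42, 0 and 1 adjusted over the list alone, camera adjusted p = 0.384). Of 5 glioma, neural and glial markers 0 passed limma and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.844). Of 6 erythroid and megakaryocyte markers TFRC (0.45) and EPOR (0.55) rose (2 and 0 adjusted over the list alone), and that list passed fry as higher (camera adjusted p = 0.0663, fry adjusted p = 0.0107). It passed camera without oeCD300A replicate 2 (0.0400).

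Among 300 KEGG pathways, 24 passed camera at the preset correlation, 10 higher and 14 lower than the other tested genes, and 0 passed with an estimated correlation (smallest adjusted p = 0.676, with 11 at an unadjusted p under 0.05). A gene can belong to several pathways, so the 24 calls are not 24 separate results. A lower call was not always a fall, as the pathway of chemical carcinogenesis by reactive oxygen species had a mean log2 change of 0.00058. The higher ones were led by graft-versus-host disease (15 genes, mean log2 change 0.61, camera adjusted p = 1.56e-08) and allograft rejection (0.60), both rich in HLA genes, and included glycolysis and gluconeogenesis (39 genes, 0.23, camera adjusted p = 0.00236) and steroid biosynthesis (15 genes, 0.24, camera adjusted p = 0.011). The lower ones were led by oxidative phosphorylation (115 genes, -0.10, camera adjusted p = 1.56e-08) and included lysosome (106 genes, -0.03, camera adjusted p = 0.0135) and ribosome (126 genes, -0.03, camera adjusted p = 0.0331). Pathways near the fixed lists that did not pass were antigen processing and presentation (41 genes, 12 rose and none fell, mean 0.19, camera adjusted p = 0.426), HIF-1 signalling (69 genes, 9 rose and 4 fell, 0.11, camera adjusted p = 0.723) and ribosome biogenesis (70 genes, 1 rose and 1 fell, camera adjusted p = 0.186). The number passing was 15 without oeCD300A replicate 1.

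By position, 1 stretch of chromosome 1 held 45 of the 459 higher genes (9.80%) while holding 0.731% of the tested genes. Between 108261196 and 120841481 (GRCh38), 103 of 112 tested genes had a positive log2 change, with a median of 0.38, and 1 fell. The rise was uneven, as the first 56 genes had a median of 0.49 and 30 of them rose, while the last 56 had 0.26 and 15 rose. The median log2 level of these genes relative to the vector mean was 0.35, 0.43 and 0.40 in oeCD300A replicates 1, 2 and 3, and between -0.04 and 0.03 in the vector libraries. The 40 tested genes before the stretch had a median of -0.06 and the 40 after it 0.17. The start was set where the running median of 21 genes rose above 0.2, but the end by the edge of a fixed run of 100 genes. Genes with little rise may thus have been counted in the last part, and the sharpness of start and end cannot be compared. PHGDH, ATP5PB and SLC16A1 lie inside it, and CD300A lies on another chromosome. Without the genes of the stretch, 394 genes were higher and 264 lower.

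**Figure D3:**
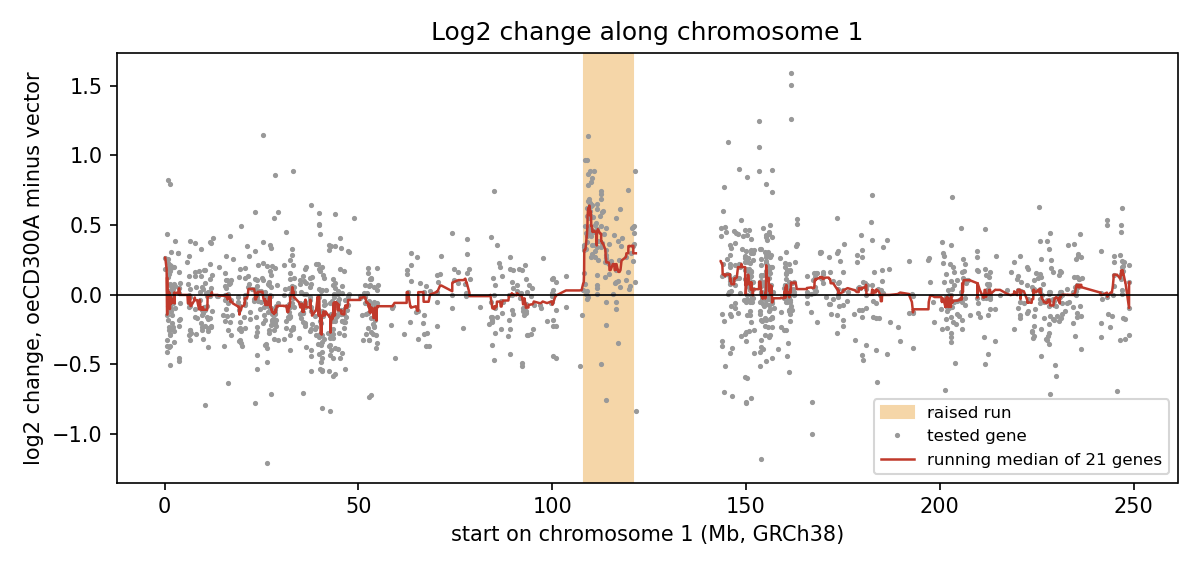
Log2 change (oeCD300A minus vector) of each tested gene against its start on chromosome 1 in Mb (GRCh38), as grey points, with the running median of 21 genes as a red line and the raised stretch shaded. The running median steps up at the start of the stretch, in which 103 of 112 genes had a positive change, and is lower in its later part.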

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

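Protein-coding genes only, GC and length correction and leaving out the chromosome 1 run were chosen after the data were seen. No gene called in the main comparison changed sign in any of the 20 other settings of the gene test in which it was tested. This was nearly fixed beforehand, because the settings reuse the libraries in which these genes were called. Of the 733 calls, 98 stayed without vector replicate 1. CD300A was higher in every setting, with adjusted p above 0.05 without a filter (log2 change 0.79, 0.0512), and the log2 change lay between 0.68 (without oeCD300A replicate 1) and 0.86 (without vector replicate 3) when libraries were left out in turn, with 0.77 (0.0721) without vector replicate 1 and 0.75 (0.0643) without vector replicate 2. Of the 95 named genes other than CD300A that passed, 33 passed in every setting, and of the 14 lists 12 did, camera with an estimated correlation set aside. Higher and lower genes numbered 136 and 92 without a filter, where 35414 genes were tested, and 1384 and 948 with library quality weights. They were 1120 and 802 after GC and length correction, and the lower genes were 442 with median-ratio scaling and 431 with quantile normalization. With 1 library left out in turn the numbers ran from 67 to 830 higher and from 32 to 779 lower, the highest without oeCD300A replicate 1. Genes changed at least 2-fold numbered 100 at a pseudocount of 0.1, 88 at 0.5 and 34 at a mean TPM of at least 5. Lists passing fell to 1 and pathways to 0 with an estimated correlation. Pathways numbered 13 at a mean TPM of at least 5, 14 with quantile normalization, 14 with library quality weights, 12 after GC and length correction and 15 without oeCD300A replicate 1, at the low end of a range up to 23. With the replicate block the counts were 124 higher and 68 lower, and the erythroid and megakaryocyte list passed camera (adjusted p = 0.0470). The replicate numbers showed no clear pairing of the samples: same-number deviations correlated at -0.06, 0.08 and -0.09, and only replicate 2 correlated best with its own number in both directions. So few libraries cannot exclude a pairing. The smaller count with the block is not read as a sign of a weaker effect. Apart from the fewer genes or samples of some settings, the cause of these moves was not tested. TPM holds no depth, so precision at low values is unknown.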

Other observations

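Tests written only after the result was seen were those of the hypoxia lists without oeCD300A replicate 1 and by library, of swapped labels, and of other splits of the libraries for the counts of changed genes, 2-fold changes and lists. The chromosome 1 run came to light in a search for runs of neighbouring genes that had been written, with its threshold, for a different pattern (genes seen in 1 group and nearly absent from the other). The bounds of the run and the other tests on it were chosen after it was seen, as was the correction for GC content and length.

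Single members of several other lists passed limma, though none of these lists passed camera in the main setting. Of 23 NRF2 oxidative stress genes, the quinone reductase NQO1, from 43.4 to 63.3 TPM (log2 change 0.54), AKR1C1 (1.11) and ME1 (0.42) rose and none fell (4 and 0 adjusted over the list alone). That list did not pass camera (adjusted p = 0.0663) but passed fry as higher (adjusted p = 0.0435). It passed camera with no filter (0.0162), after quantile normalization (0.0175), without oeCD300A replicate 2 (0.0356) and after GC and length correction (0.0371). Of 23 immediate early genes the nuclear receptor NR4A1, from 3.30 to 7.53 TPM (0.98), and KLF2 (0.75) rose (4 and 0 adjusted over the list alone, camera adjusted p = 0.624). Of 17 heat shock genes HSP90AB1 (0.24) and HSP90AA1 (0.37) rose (2 and 1 adjusted over the list alone, camera adjusted p = 0.624). Of 44 interferon-stimulated genes XAF1 (0.66) and SAMD9L (0.68) rose and IFI27 (-0.50) fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.363), and the list passed fry as higher (adjusted p = 0.0487). Of 25 tumour-promoting secreted factors and matrix genes 3 rose and 3 fell (4 and 5 adjusted over the list alone), with VEGFA higher and TIMP1 and the galectin LGALS1 (-0.37) lower. The mean of that list was 0.01 with a downward camera test that did not pass (adjusted p = 0.367).

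Further lists also did not pass camera in the main setting. Of 13 granulocyte precursor genes the transcription factor MYB rose (0.43) and the receptor KIT fell (-0.52) (2 and 3 adjusted over the list alone, adjusted p = 0.149). Of 40 S phase genes RAD51AP1 (0.45) and SLBP (0.29), which binds histone mRNAs, rose (2 and 0 adjusted over the list alone, adjusted p = 0.486). Of 21 p53 targets PHLDA3 (-0.68) and AEN (-0.54) fell (0 and 2 adjusted over the list alone, adjusted p = 0.0711). The p53 list passed as lower without the eBayes trend (0.0494), without vector replicate 2 (0.0440) and with protein-coding genes only (0.0481), while its mean in oeCD300A replicate 1 (3.956) lay within the vector range of 3.907 to 3.982. CCL23 (-0.61) alone fell among 9 chemokines (0 and 1 adjusted over the list alone, adjusted p = 0.38). Of 22 NF-kB targets PTX3 fell (-0.54; 0 and 1 adjusted over the list alone, adjusted p = 0.721), though 15 were positive and 7 were higher against 2 lower at an unadjusted p under 0.05. Of 21 integrins and adhesion genes ITGB7 fell (-0.82), with 5 and 4 adjusted over the list alone (adjusted p = 0.606). Of 50 cytosolic ribosomal protein genes 0 passed limma and 9 had an unadjusted p under 0.05, 5 higher and 4 lower (camera adjusted p = 0.234). This list passed as lower after median-ratio scaling (0.0391), without oeCD300A replicate 2 (0.0195) and without oeCD300A replicate 3 (0.0168). Its mean was lower in oeCD300A replicate 1 alone (11.503), and in oeCD300A replicates 2 and 3 (11.654 and 11.643) it lay above the vector range of 11.595 to 11.617.

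The most regional pattern was the run of raised genes on chromosome 1, between 108261196 and 120841481 (GRCh38). Of 129 runs of 100 neighbouring genes over all chromosomes, the run starting at 109087971 had the largest median log2 change in size, 0.374, and the next, on chromosome 10, had 0.202. In 1000 shuffles of the gene order the largest run median in size was 0.167, which argues against a chance order. Runs on chromosome 10 (0.202 and 0.179) and chromosome 6 (0.186 and 0.182) exceeded that value as well, so smaller shifts were not confined to chromosome 1. They were not confined to short regions either, as every run of chromosome 10 had a median between 0.132 and 0.202. Every run of chromosome 5 lay between 0.101 and 0.158, and every run of chromosome 11 between -0.111 and -0.017. BNIP3, P4HA1 and AKR1C1 lie on chromosome 10 and HMGCS1 and STARD4 on chromosome 5, with log2 changes above these medians. Without oeCD300A replicate 1 the median of the raised genes on chromosome 1 was 0.42, so that library alone does not account for their rise. A candidate explanation is a copy-number difference between the cells of the 2 groups, for which the search had set a run median of at least 0.25 beforehand, against the 0.374 found. Regional control of transcription stays open, as no DNA measurement was analysed here. The last 56 genes of the run had a median of 0.26 against 0.49 in the first 56. The 40 genes after it still had 0.17. These values do not decide between the explanations, because the end was set by the edge of a fixed run of 100 genes. If the populations differ in copy number, part of the other differences may also reflect separate histories of the cells and not CD300A.

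The joint rise of hypoxia and glycolysis genes did not rest on oeCD300A replicate 1, since the hypoxia mean without it was 0.65 (camera adjusted p = 4.39e-16). Correction for GC content and transcript length left it at 0.65 (camera adjusted p = 2.96e-15), against 0.67 uncorrected, and the median of all tested genes was 0.0585, far below the shift of the list. The lowest oeCD300A library lay 0.613 above the highest vector library in the mean log2 level of the list. A difference in culture, such as density or medium age, and an effect of CD300A cannot be told apart here, since either would separate the groups in this way and the labels give no culture record. An effect of CD300A on hypoxia genes is therefore an untested hypothesis, and EPAS1, which encodes HIF-2α, was lower (log2 change -1.13).

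CD300A rose 1.77-fold. Its 10 tested neighbours within 300 kb had a median log2 change of -0.0175, which argues against a rise of the whole CD300 gene region. The lowest oeCD300A library lay 11.6 TPM above the highest vector library, so swapped labels are not supported by this gene. Whether the added transcripts came from the construct stays open, because TPM per gene does not separate construct from endogenous reads.

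The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 733 changed genes against 3 in the highest other split, 57 genes changed at least 2-fold against 3, 14 lists against 8 and 24 pathways against 12, and in each case 1 of the 10 splits, the real one, reached the real value. Every other split still called 4 to 8 lists and 1 to 12 pathways at the preset correlation, with 0 to 3 changed genes. Each of them held the groups in unequal shares, so part of the real difference remained and these counts do not measure chance alone. Genes at 1 TPM or more in all libraries of 1 group and under 0.05 TPM in all of the other were 5 in the real split, against 10 in the highest other, and 6 of the 10 splits gave as many. Among these 5, named after their values were seen, the antisense RNA ARAP1-AS1 had 3.66, 3.64 and 2.92 TPM with the vector and was listed at 0 in every oeCD300A library.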
